A study of Homo sapiens with 21 samples.

How the data were processed

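Of 21 samples in the series, the 9 RNA-seq libraries of H1975 were used, with 3 in each of the groups DMSO_EV, Osi_Lin_EV and Osi_cIGF1R, as the labels put them. The 12 circular RNA libraries were not analysed here. The deposited table gave 34021 genes by symbol, with a column per library, each matched to its sample by name. Of these, 913 genes were at 0 in every library. The unit of the deposited values is not named in the file: fractional values and column totals of 338034 to 474156 that differ between libraries point to FPKM, made by the authors from fragment counts, gene length and library size. The low values showed no steps of whole reads, so read depth is unknown and no counting interval was computed. Per the submitters' processing notes, Bowtie2 2.1.0, STAR, edgeR and the build hg38 were used, with no role or order named. The counter, the annotation, the use of strand and any filter are not given in the sources used here. The labels of all 21 samples, RNA-seq included, carry 1 extraction protocol, which names RNase R, an enzyme that digests linear RNA, and a treatment of 3 days, whereas the RNA-seq samples are labelled as cultured for 8 days. Whether the RNA-seq libraries had RNase R is therefore not settled by the labels. With it, levels of linear mRNA would depend on their resistance to the enzyme. Because FPKM is a share of each library, a few abundant transcripts that change, such as those of mitochondrial DNA, shift all the others. Gene positions are those of the RefSeq annotation of GRCh38, in which 31617 of the symbols (92.9%) had a match. A further 15 older symbols of list members were matched by hand.

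Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes with a trend in the mean and robust variance), in 1 fit over the 9 libraries. A fold change on this scale understates the change of low genes. The 13775 genes with an FPKM of at least 1 in at least 3 libraries were tested, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. This is the branch for normalized values of the design written before the data were examined. Count tests were not run, since the values are not counts. The 3 comparisons were Osi_Lin_EV with DMSO_EV, Osi_cIGF1R with DMSO_EV, and Osi_cIGF1R with Osi_Lin_EV. For 31 gene lists fixed before the data were examined, camera in limma compared the members with all other genes, with a preset correlation between genes of 0.01, two-sided, in lists with at least 5 tested members. Of these, 29 lists qualified. Camera was repeated with an estimated correlation, and fry was run as another set test. Named genes followed a rule fixed in advance: per comparison the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM, up to 3 called members per list with the largest change, and 6 genes of the design. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule named are not reported here. The overlap of both treated groups was set beside 20 simulations of unchanged groups against the same controls. The limma step was tested on simulated data over 13775 genes: of 100 genes changed by 1 on the log2 scale it recovered 97, 96 and 97 in the comparisons in the order above, and all 100 changed by 2 in each, with 11 of 208, 5 of 201 and 12 of 209 calls false. The changed genes were drawn only from those with higher levels in DMSO_EV, so recovery was not measured for genes near the filter. They were also far fewer than the 52.6%, 69.0% and 60.7% of genes called in the real comparisons, and noise was independent between genes. The rates of recovery and of false calls may therefore differ in the real data. In simulated lists, camera called the 1 shifted list in each comparison, and 0, 1 and 0 of the others. The simulated genes varied independently, so these lists cannot show how often camera calls falsely where members vary together. Alternatives set before the data were examined were limma without a trend, median-of-ratios rescaling, quantile normalization of genes, no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 5, a fit of the compared groups only, a replicate block, an absolute log2 fold change of 1, and leaving out each replicate. Rescaling to equal totals without mitochondrial genes, and quantile normalization for the lists, were added after seeing the data. Another 7 lists were drawn up after seeing the data, and their results stand among the other observations. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 drew the figures.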

Results

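RNA sequencing profiled H1975, an established cell line from a human lung adenocarcinoma that carries mutations in EGFR, the epidermal growth factor receptor gene, in 3 groups of 3 libraries after 8 days of culture. The group DMSO_EV received vehicle (DMSO) with EV, a label that the submitters did not spell out. Osi_Lin_EV received EV with 500 nM osimertinib, a covalent inhibitor of mutant EGFR, and 500 nM linsitinib, an inhibitor of the kinases of the insulin-like growth factor receptor IGF1R and of the insulin receptor. Osi_cIGF1R received 500 nM osimertinib together with overexpression of cIGF1R, a circular RNA made from IGF1R. The file names no unit. Its values point to FPKM, the fragments counted at a gene scaled to the length of the gene and to the size of the library. The FPKM totals were 447564 ± 23507 in DMSO_EV, 429016 ± 4983 in Osi_Lin_EV and 354042 ± 23735 in Osi_cIGF1R (SD, n = 3). The labels do not settle whether these libraries were treated with RNase R, which digests linear RNA and would make the levels of linear mRNA depend on their resistance to it. Read depth per library is unknown, so no counting interval could be given. Across the 13775 genes tested, Pearson's r of log2 values between libraries of 1 group lay between 0.986 and 0.994, and between libraries of different groups between 0.817 and 0.929. Genes are not independent replicates. In a principal component analysis, the first component held 69.4% of the variance and the second 22.8%. Scores on the first ran from -56.8 to -50.6 in DMSO_EV, from -12.4 to -9.44 in Osi_Lin_EV and from 61.6 to 66.2 in Osi_cIGF1R. DMSO_EV replicate 2 stood apart on noncoding RNAs transcribed by RNA polymerase III, named here after their values were seen: it held 443 FPKM of RN7SL1, 177 of RN7SK and 162 of RMRP, against 46.4, 11.5 and 11.4 in replicate 1 and 36.1, 9.43 and 6.87 in replicate 3. Osi_cIGF1R replicate 1 also stood apart, with 53.2, 17.1 and 2.18 FPKM of these RNAs in the same order. Replicate 2 of that group held 3.16, 0.913 and 0, and replicate 3 held 6.37, 1.96 and 0. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

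**Figure D1:**
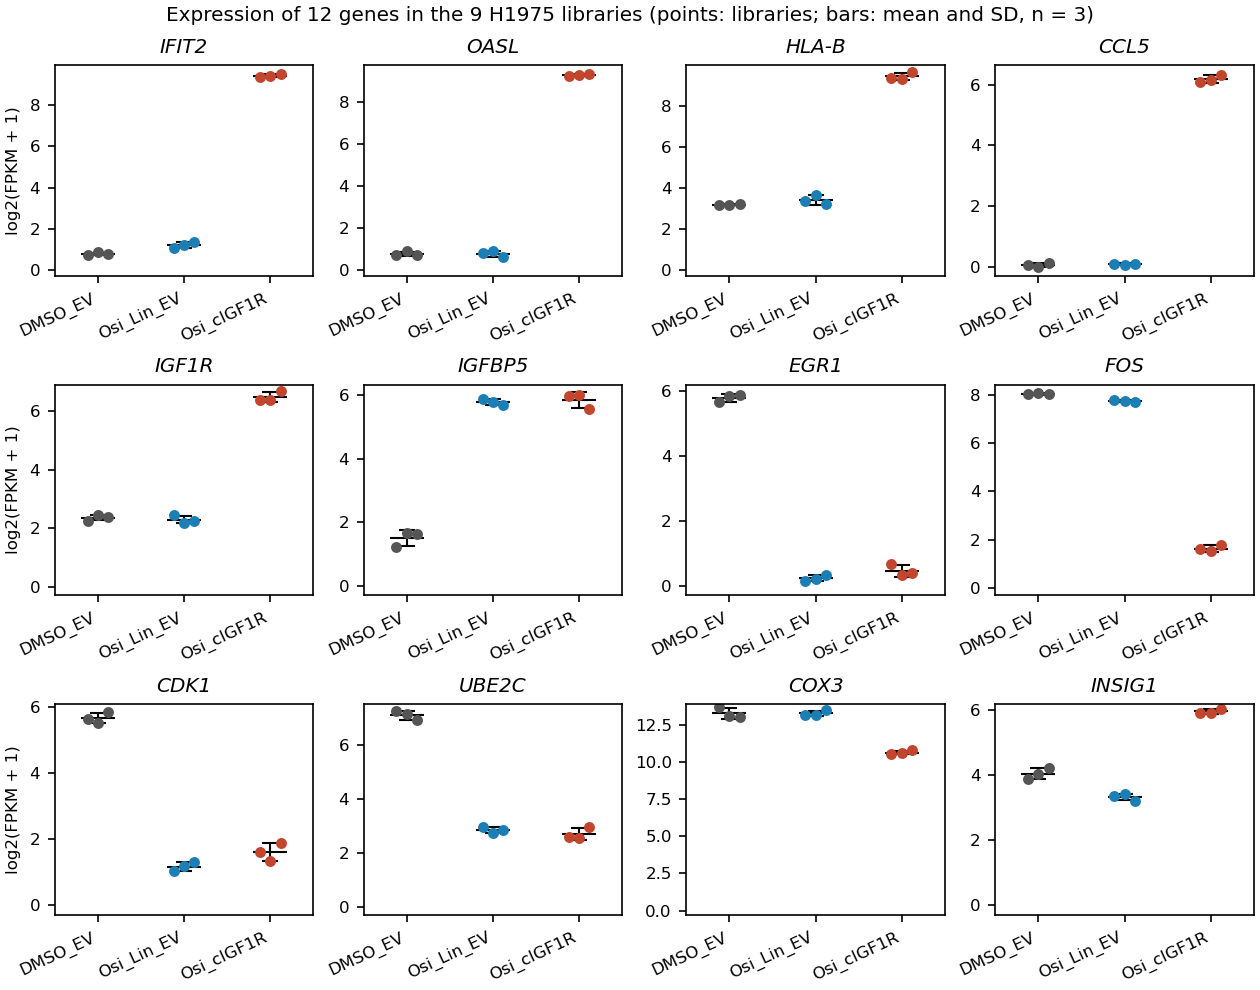
Expression of 12 genes as log2(FPKM + 1) in each of the 9 libraries of the groups DMSO_EV, Osi_Lin_EV and Osi_cIGF1R; points are libraries, and bars give the mean and SD (n = 3). IFIT2, OASL, HLA-B, CCL5, IGF1R and INSIG1 were higher in the 3 Osi_cIGF1R libraries than in the 6 others, and EGR1, CDK1 and UBE2C were lower in both treated groups than in DMSO_EV.

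The comparison of Osi_Lin_EV with DMSO_EV asked how cells that lived through 8 days of osimertinib and linsitinib differed from vehicle-treated cells. Cell-cycle genes and outputs of the ERK kinase pathway had fallen, and IGFBP5, which encodes a binding protein of insulin-like growth factors, had the largest rise under the naming rule. IGFBP5 stood at 54.2 ± 3.51 FPKM in Osi_Lin_EV and 1.86 ± 0.468 in DMSO_EV (SD, n = 3), a ratio of 29.1. EGR1, an immediate early transcription factor induced through ERK, stood at 0.174 ± 0.0793 against 54.1 ± 4.38 FPKM, and CDK1, the kinase that drives entry into mitosis, at 1.24 ± 0.219 against 49.6 ± 5.7. In all, 3999 genes rose and 3242 fell of 13775 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 503 and 763 of these passed an absolute log2 fold change of 1. The balance turned under median-of-ratios rescaling, to 3575 higher and 3696 lower.

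The 8 largest rises under the naming rule were led by IGFBP5 (log2 fold change 4.28, SE 0.14, limma adjusted p = 4.21e-11). The others were ATG9B, a homologue of the autophagy membrane protein ATG9A (2.92), VTCN1, an inhibitory ligand of T cells (2.87), ATP6V1B1, a subunit of the proton pump of acidic compartments (2.86), the apolipoprotein gene APOD (2.83), NPNT, an extracellular matrix protein (2.77), the small GTPase gene RHOB (2.51) and BMF, a pro-apoptotic member of the BCL2 family (2.45). VTCN1 reached 13.3 ± 0.809 FPKM from 0.949 ± 0.107, and BMF 57.1 ± 1.07 from 9.62 ± 0.504 (SD, n = 3). The 8 largest falls were led by EGR1 (log2 fold change -5.55, SE 0.11, limma adjusted p = 5.39e-12). CDK1 followed at -4.496, then UBE2C, a ubiquitin-conjugating enzyme of mitotic exit (-4.26), the cell-cycle transcription factor MYBL2 (-4.26), the transglutaminase TGM2 (-4.21), the mitotic kinase AURKB (-4.19), the mitotic kinesin KIF20A (-4.19) and FOSL1, a member of the AP-1 transcription factor family (-4.17). Pseudocounts of 5 and 0.1 in place of 1 gave log2 fold changes of 1.62 and 3.68 for VTCN1, 1.57 and 3.75 for ATP6V1B1, 1.44 and 3.78 for NPNT, -3.51 and -7.67 for EGR1, -2.52 and -5.51 for TGM2 and -2.66 and -5.13 for FOSL1.

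All 30 mitosis and G2/M genes fell, with a median log2 fold change of -3.27 (camera adjusted p = 2.86e-30). UBE2C dropped to 6.25 ± 0.552 FPKM from 139 ± 16 and AURKB to 1.77 ± 0.422 from 49.3 ± 4.77 (SD, n = 3). The 30 DNA replication and G1/S genes also fell without exception (median -1.94, camera adjusted p = 3.71e-23), among them RRM2, a subunit of ribonucleotide reductase (-4.12), the thymidylate synthase TYMS (-3.93) and the replication factor CDC45 (-3.44). With pseudocounts of 5 and 0.1 the log2 fold changes were -2.54 and -5.21 for RRM2, -2.22 and -5.404 for TYMS and -1.64 and -5.94 for CDC45. Every one of the 30 MYC and ribosome-biogenesis genes fell (median -1.16, camera adjusted p = 1.33e-16), for example PAICS, an enzyme of purine synthesis (-1.92), NOP16 (-1.82) and the nucleolar protein NOLC1 (-1.68). Of 26 ERK pathway feedback and output genes, 24 fell and 2 rose (median -1.75, camera adjusted p = 7.83e-16). The phosphatase DUSP4 went from 19.8 ± 1.79 to 0.404 ± 0.174 FPKM. These calls hold with an estimated correlation, at adjusted p = 0.014 for mitosis, 0.0304 for replication, 0.00682 for MYC and 0.00424 for ERK outputs.

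FOXO target genes, which transcription factors restrained by AKT switch on, rose in 16 of 21 cases, fell in 2 and did not pass in 3. The list had a median log2 fold change of 0.71 (camera adjusted p = 6.51e-05, adjusted p = 0.235 with an estimated correlation). TSC22D3 reached 26.3 ± 3.05 FPKM from 4.45 ± 1.01, the muscle-atrophy ubiquitin ligase FBXO32 12.7 ± 0.278 from 2.79 ± 0.233 and CITED2 73.1 ± 2.52 from 22.2 ± 2.95 (SD, n = 3). Of 31 lysosomal genes 16 rose, 1 fell and 14 did not pass. The members' median log2 fold change was 0.35 (camera adjusted p = 0.00171, adjusted p = 0.703 with an estimated correlation), with the protease genes CTSF (1.81) and CTSH (1.14) up and the galactosidase GLA down (-1.28). Among 36 interferon-stimulated genes 22 rose, 1 fell and 13 did not pass, with a median of 0.39 (camera adjusted p = 0.000525, adjusted p = 0.0483 with an estimated correlation). The antiviral GTPase MX1 stood at 4.25 ± 0.35 FPKM against 1.34 ± 0.183, and IRF9, a subunit of the interferon-activated factor ISGF3, at 41.6 ± 1.22 against 15.8 ± 2.57. MHC class I antigen presentation genes rose in 10 of 16 cases, fell in 1 and did not pass in 5. As a list they had a median log2 fold change of 0.49 (camera adjusted p = 0.0234, adjusted p = 0.703 with an estimated correlation). The immunoproteasome subunit PSMB10 rose by 1.12 and the peptide transporter TAP2 fell by 0.88 on the log2 scale. Replication-dependent histone genes, whose messages largely lack poly(A) tails, rose in 7 of 13 cases, fell in 1 and did not pass in 5. On the log2 scale their median change was 0.78 (camera adjusted p = 0.0388, adjusted p = 0.23 with an estimated correlation), and H1-2 reached 33.1 ± 2.74 FPKM from 8.06 ± 1.44. The histone call ended under quantile normalization (camera adjusted p = 0.053) and without Osi_cIGF1R replicate 3 (0.065), with a range of 0.000611 to 0.23 over the camera alternatives. The histone median was 1.38 and 1.57 without DMSO_EV replicate 1 and 2, 1.48 without Osi_cIGF1R replicate 1 and 1.73 under the filter at 5 FPKM.

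Cholesterol synthesis genes fell in 15 of 24 cases, rose in 2 and did not pass in 7. The median over the tested members was -0.37 (camera adjusted p = 0.00235, adjusted p = 0.703 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum that the rule named in the other comparisons, dropped to 9.04 ± 0.704 FPKM from 15.6 ± 2.03 (SD, n = 3; limma adjusted p = 6.53e-05), while the sterol reductase TM7SF2 rose by 1.98 on the log2 scale. ATF4 and amino-acid response genes fell in 15 of 26 cases, rose in 4 and did not pass in 7. Together they had a median log2 fold change of -0.44 (camera adjusted p = 0.000525, adjusted p = 0.235 with an estimated correlation), including the serine synthesis enzymes PSAT1 (-2.04) and PHGDH (-1.71). Nuclear-encoded oxidative phosphorylation genes fell in 21 of 44 cases, rose in 1 and did not pass in 22. Over the list the median log2 fold change was -0.27 (camera adjusted p = 0.000579, adjusted p = 0.703 with an estimated correlation). Cytochrome c (CYCS) stood at 4.51 ± 0.243 FPKM against 13.8 ± 0.826. None of the 13 mitochondrial DNA-encoded mRNAs passed the limma test, and 0 of them had an adjusted p under 0.05 when adjusted over the list alone (median -0.21, camera adjusted p = 0.428). Over the alternatives that median ran from -0.317 to 0.0486.

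Camera did not call the other lists in this comparison, although single members changed. Glycolysis and hypoxia genes rose in 6 and fell in 17 of 30 cases (camera adjusted p = 0.0602), with the glycolytic enzyme ENO1 at 383 ± 34.1 against 860.3 ± 105 FPKM. Senescence-associated genes rose in 6 and fell in 13 of 21 cases (camera adjusted p = 0.0602), and the lamin LMNB1 dropped to 1.44 ± 0.257 from 25.6 ± 2.66 FPKM. Of 21 mesenchymal genes 4 rose and 9 fell (camera adjusted p = 0.0735), the adhesion receptor CD44 from 106 ± 9.93 to 27.8 ± 0.186 FPKM. Mitophagy receptors and regulators rose in 9 and fell in 6 of 28 cases (camera adjusted p = 0.661), autophagy core genes in 11 and 3 of 28 (camera adjusted p = 0.117), and ULK1, the kinase that starts autophagy, reached 51 ± 0.684 from 19.2 ± 1.51 FPKM. NF-kB and inflammatory cytokine genes rose in 6 and fell in 6 of 21 cases (camera adjusted p = 0.686), among them the neutrophil chemokine CXCL8, which dropped to 3.69 ± 0.75 from 39 ± 5.71 FPKM. In the list of IGF and insulin receptor signalling 4 rose and 6 fell of 17 (camera adjusted p = 0.805), and in that of ERBB receptors and ligands 3 and 3 of 11 (camera adjusted p = 0.633), where the EGFR inhibitor gene ERRFI1 fell by 2.73 on the log2 scale. Counts of members up and down were 10 and 2 of 29 for epithelial and keratin genes (camera adjusted p = 0.428), 9 and 3 of 20 for genes named as persister-cell markers (camera adjusted p = 0.154), and 6 and 9 of 25 for p53 target genes (camera adjusted p = 0.516). They were 5 and 4 of 15 for BCL2 family genes (camera adjusted p = 0.481), 10 and 6 of 22 for YAP and TEAD target genes (camera adjusted p = 0.686) and 4 and 10 of 28 for circular RNA biogenesis and m6A factors (camera adjusted p = 0.117). Over the scalings 2 to 5 epithelial genes fell, 2 to 4 circular RNA factors rose, and 1 to 2 oxidative phosphorylation genes and 1 to 2 cholesterol synthesis genes rose. Calls appeared under some alternatives: for glycolysis and senescence with equal totals without mitochondrial genes (camera adjusted p = 0.035 and 0.0457), for mesenchymal genes under the filter at 5 FPKM (0.0388), and without single libraries. The latter held for glycolysis without DMSO_EV replicate 1 or 3 (camera adjusted p = 0.018 and 0.0428; range over the camera alternatives 0.018 to 0.703), for mesenchymal genes and circular RNA factors without DMSO_EV replicate 1 (0.0166 and 0.0369; ranges 0.0166 to 0.703 and 0.0369 to 0.703) and for senescence without Osi_Lin_EV replicate 2 (0.0498; range 0.0457 to 0.703). Over all listed markers of other cell types the medians were 0.111 FPKM for alveolar epithelial cells, 0.0157 for fibroblasts, 0.0919 for leukocytes and 0.0282 for endothelial cells in Osi_Lin_EV, against 0.0775, 0.0307, 0.0591 and 0.0193 in DMSO_EV. The most abundant markers in Osi_Lin_EV, in the same order, were LPCAT1 at 50.9, COL5A1 at 44.7, CD68 at 25 and ESAM at 1.62 FPKM, and in DMSO_EV CAV1 at 53.1, COL5A1 at 29.01, CD68 at 25.1 and CDH5 at 3.37. Of the alveolar markers 3 rose and 1 fell of 6 tested (camera adjusted p = 0.58), and of the leukocyte markers 2 and 0 of 6 (camera adjusted p = 0.661). Fibroblast markers changed in 1 of 4 and endothelial markers in 1 of 2, too few for camera. Over the scalings 1 to 2 alveolar markers fell, and 0 to 1 of the mitochondrial mRNAs rose.

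Of the genes fixed for their role in the design, IGF1R (chromosome 15 from 98648539 to 98964530, GRCh38) stood at 3.9 ± 0.445 FPKM in Osi_Lin_EV and 4.13 ± 0.336 in DMSO_EV (SD, n = 3; limma adjusted p = 0.616). INSR, the insulin receptor gene (chromosome 19 from 7112265 to 7294414), rose from 1.39 ± 0.0694 to 2.21 ± 0.143 FPKM (limma adjusted p = 0.0044). EGFR (chromosome 7 from 55019017 to 55211628) did not pass at 38.4 ± 2.8 against 52.3 ± 8.14 FPKM (limma adjusted p = 0.058). It passed without DMSO_EV replicate 1 (limma adjusted p = 0.0388) and without Osi_cIGF1R replicate 1, 2 or 3 (0.0447, 0.0484 and 0.00558), and also under median-of-ratios rescaling (0.0318), the filter at 5 FPKM (0.0373) and a fit of the compared groups only (0.0101), with a range of 0.00558 to 0.198 over the alternatives. PINK1, the kinase that marks damaged mitochondria (chromosome 1 from 20633458 to 20651511), rose from 12.2 ± 2.25 to 23 ± 2.46 FPKM, and VDAC1, a channel of the outer mitochondrial membrane (chromosome 5 from 133971871 to 134114540), fell from 122 ± 14.3 to 68.5 ± 4.41 (limma adjusted p = 6.05e-05 and 2.14e-05). Camera called 12 of 29 lists tested, 5 up and 7 down, and 5 of the 12 calls hold with an estimated correlation. Adjusted over the list alone, the number of called members was the same as over all genes in 25 of 31 lists. It was 7 in place of 6 for ERBB receptors and ligands, 20 in place of 22 for oxidative phosphorylation, 24 in place of 23 for interferon-stimulated genes, 20 in place of 19 for senescence, 21 in place of 19 for ATF4 and 5 in place of 4 for alveolar markers. The list median, mean and camera direction differed in sign for IGF and insulin receptor signalling (-0.088, 0.15, down), NF-kB genes (0.022, -0.19, down), YAP and TEAD targets (0.26, -0.051, up) and leukocyte markers (-0.064, 0.17, up), none of them called. Over the alternatives the leukocyte median ran from -0.293 to 0.00652 and the NF-kB median from -0.00188 to 0.0661.

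The comparison of Osi_cIGF1R with DMSO_EV asked how cells kept in osimertinib with cIGF1R overexpression differed from vehicle-treated cells. No group with osimertinib and EV alone was analysed here, so the drug and the circular RNA changed together. The 8 largest rises were those of interferon-stimulated genes: IFIT2, which encodes an RNA-binding antiviral protein, stood at 691 ± 29.7 FPKM against 0.707 ± 0.079 (SD, n = 3). HLA-B, a peptide-presenting MHC class I chain, reached 698 ± 94.9 FPKM from 8.1 ± 0.226, a ratio of 86.1. FOS, an immediate early AP-1 gene, fell to 2.13 ± 0.279 from 263 ± 6.63 FPKM, the cell-cycle genes fell as a group, and the mRNAs encoded by mitochondrial DNA were lower, with COX3 at 1586 ± 146 against 10097 ± 2887. With an estimated correlation the camera call of the mitosis list held (adjusted p = 0.0395), and those of the DNA replication list (adjusted p = 0.0649) and of the mitochondrial mRNAs (adjusted p = 0.447) did not. In all, 4563 genes rose and 4936 fell of 13775 tested (limma, adjusted p under 0.05), and 1433 and 1571 of these passed an absolute log2 fold change of 1. The balance turned with equal totals without mitochondrial genes (4715 higher and 4642 lower) and without DMSO_EV replicate 3 (4575 higher and 4473 lower).

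IGF1R, the gene that cIGF1R is made from, was listed at 88.2 ± 11 FPKM in Osi_cIGF1R and 4.13 ± 0.336 in DMSO_EV (SD, n = 3), a ratio of 21.3 (log2 fold change 4.11, SE 0.11, limma adjusted p = 1.52e-12). The table gives a value per gene, so reads from a circular transcript and from the linear mRNA could not be separated, and no level of cIGF1R itself is given. The counting is not stated to use strand in the sources used here. IRAIN, an antisense transcript within IGF1R named after its values were seen, was listed at 0.0117 ± 0.00413 FPKM in Osi_cIGF1R and 0.0464 ± 0.025 in DMSO_EV. INSR rose from 1.39 ± 0.0694 to 2.09 ± 0.385 FPKM (limma adjusted p = 0.00838), and EGFR, at 43.3 ± 11.2 against 52.3 ± 8.14, did not pass (limma adjusted p = 0.158). PINK1 rose by 0.86 on the log2 scale to 22.7 ± 0.884 FPKM, and VDAC1 fell by 1.28 to 49.7 ± 2.84 FPKM (limma adjusted p = 3.51e-05 and 1.39e-07).

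The 8 largest rises were all members of the interferon-stimulated list: IFIT2 (log2 fold change 8.66, SE 0.093, limma adjusted p = 1.18e-15), IFI27 (8.62), OASL (8.51), IFITM1, a membrane protein that blocks virus entry (8.18), IFI6 (8.16), IFIT1 (7.91), IFIT3 (7.901) and OAS2, an antiviral enzyme activated by double-stranded RNA (7.69). In FPKM, OASL stood at 617 ± 12.8 against 0.697 ± 0.124, IFI6 at 1551 ± 321 against 4.36 ± 0.185 and IFITM1 at 1407 ± 162 against 3.85 ± 0.299 (SD, n = 3). All 36 interferon-stimulated genes rose, with a median log2 fold change of 5.29 (camera adjusted p = 1.94e-27, adjusted p = 0.000862 with an estimated correlation). Together they made up 4.52% ± 0.24 of the FPKM total in Osi_cIGF1R and 0.081% ± 0.00463 in DMSO_EV. All 16 MHC class I antigen presentation genes rose. Their median log2 fold change was 3.15 (camera adjusted p = 1.91e-11, adjusted p = 0.0649 with an estimated correlation), including HLA-F at 124 ± 22.3 against 1.9 ± 0.467 FPKM and the peptide transporter TAP1 at 226 ± 8.08 against 11.1 ± 1.95. HLA genes, IFITM1, the IFIT genes and histone genes resemble their paralogues in sequence, and how shared reads were counted is not given in the sources used here. NF-kB and inflammatory cytokine genes rose in 10 of 21 cases, fell in 7 and did not pass in 4 (median 0.16, camera adjusted p = 0.185; 0.0341 with a median of 0.79 under the filter at 5 FPKM, with a range of 0.0341 to 0.753 over the camera alternatives). The lowest NF-kB median over the alternatives was -0.018. The T-cell chemokine CCL5 reached 71.5 ± 6.5 FPKM from 0.0447 ± 0.0434, CXCL10 16.8 ± 2.21 from 0.0294 ± 0.0261, and CXCL11 10.8 ± 1.37 where DMSO_EV is listed at 0 in each library. Beside these groups, CD68, a macrophage marker of endolysosomes, rose from 25.1 ± 3.51 to 428 ± 15.2 FPKM, and LAMP3, listed with alveolar cells, from 1.88 ± 0.452 to 198 ± 14.4. Over all leukocyte markers the median was 0.173 FPKM in Osi_cIGF1R and 0.0591 in DMSO_EV, and PTPRC, which encodes the pan-leukocyte antigen CD45 and was named after its values were seen, was listed at 0.0117 ± 0.0203 and 0.0104 ± 0.00977 FPKM.

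The 8 largest falls were FOS (log2 fold change -6.403, SE 0.091, limma adjusted p = 4.9e-15), FOSB (-5.45), EGR1 (-5.32), the secreted trefoil peptide TFF1 (-4.801), MYBL2 (-4.75), RRM2 (-4.42), UBE2C (-4.41) and CDC20, an activator of the ubiquitin ligase of mitotic exit (-4.24). FOSB went from 72 ± 14.5 to 0.644 ± 0.0432 FPKM and TFF1 from 31.6 ± 5.56 to 0.164 ± 0.146 (SD, n = 3). Of 26 ERK pathway feedback and output genes 23 fell, 1 rose and 2 did not pass. The list had a median log2 fold change of -1.76 (camera adjusted p = 2.63e-10, adjusted p = 0.00774 with an estimated correlation). All 30 mitosis and G2/M genes fell. The members' median log2 fold change was -3.095 (camera adjusted p = 4.64e-18, adjusted p = 0.0395 with an estimated correlation), and CDC20 went from 84.9 ± 3.87 to 3.55 ± 0.147 FPKM and CDK1 from 49.6 ± 5.7 to 2.07 ± 0.596. The 30 DNA replication and G1/S genes fell as well. As a list they had a median log2 fold change of -2.05 (camera adjusted p = 6.44e-14, adjusted p = 0.0649 with an estimated correlation), among them TYMS (-3.82) and UHRF1, which maintains DNA methylation (-3.61). With pseudocounts of 5 and 0.1 the values were -3.45 and -6.85 for EGR1, -2.81 and -7.105 for TFF1, -2.62 and -5.98 for RRM2, -2.19 and -5.08 for TYMS and -2.08 and -4.74 for UHRF1. The 30 MYC and ribosome-biogenesis genes fell without exception. On the log2 scale their median change was -1.76 (camera adjusted p = 1.42e-13, adjusted p = 0.00816 with an estimated correlation), with PAICS at 1.37 ± 0.121 against 17.9 ± 1.8 FPKM and the polyamine enzymes ODC1 (-2.89) and SRM (-2.59) down.

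All 13 mitochondrial DNA-encoded mRNAs fell, with a median of -2.28 (camera adjusted p = 8.54e-06, adjusted p = 0.447 with an estimated correlation). The fall was smaller, at a median of -1.40, under quantile normalization. COX3 had a log2 fold change of -2.64 (SE 0.19), ND6 one of -2.42 and ATP8, whose reading frame overlaps ATP6, one of -2.41. Under quantile normalization COX3 had -1.72. Together the 13 mRNAs made up 5.88% ± 0.572 of the FPKM total in Osi_cIGF1R, 20.4% ± 2.6 in Osi_Lin_EV and 21.6% ± 5.17 in DMSO_EV (SD, n = 3). Nuclear-encoded oxidative phosphorylation genes fell in 36 of 44 cases, rose in 2 and did not pass in 6. The median over the tested members was -0.84 (camera adjusted p = 7.84e-07, adjusted p = 0.447 with an estimated correlation), including the ATP synthase subunits ATP5MC1 (-2.07) and ATP5PB (-1.67) and cytochrome c (CYCS, -1.79, with -1.18 and -2.04 at pseudocounts of 5 and 0.1). Lysosomal genes rose in 23 of 31 cases, fell in 1 and did not pass in 7. Together they had a median log2 fold change of 0.92 (camera adjusted p = 1.85e-06, adjusted p = 0.447 with an estimated correlation). PSAP, the precursor of the saposins, reached 692 ± 59.8 FPKM from 168 ± 32.8. FOXO target genes rose in 19 of 21 cases, fell in 1 and did not pass in 1. Over the list the median log2 fold change was 1.21 (camera adjusted p = 8.5e-07, adjusted p = 0.107 with an estimated correlation), with TXNIP, an inhibitor of glucose uptake, at 114 ± 4.16 against 17.9 ± 3.9 FPKM. Mitophagy receptors and regulators rose in 16 of 28 cases and fell in 7, and autophagy core genes in 15 and 5 of 28, short of the threshold (camera adjusted p = 0.0711 and 0.0719). Those 2 lists passed without Osi_cIGF1R replicate 1 (camera adjusted p = 0.0387 and 0.0411) and without replicate 2 (0.0399 and 0.0352), with ranges of 0.0387 to 0.646 and 0.0352 to 0.553 over the camera alternatives. OPTN and CALCOCO2, receptors that bring ubiquitin-tagged cargo to autophagosomes, rose by 2.86 and 1.53 on the log2 scale.

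Cholesterol synthesis genes rose in 17 of 24 cases, fell in 3 and did not pass in 4. Their median log2 fold change was 0.62 (camera adjusted p = 0.00395, adjusted p = 0.447 with an estimated correlation). INSIG1 reached 61.2 ± 2.98 FPKM from 15.6 ± 2.03 and the synthase HMGCS1 37.4 ± 0.923 from 12.6 ± 0.946 (SD, n = 3). IGF and insulin receptor signalling genes, IGF1R itself among them, rose in 12 of 17 cases, fell in 2 and did not pass in 3. The list had a median log2 fold change of 0.504 (camera adjusted p = 0.00372, adjusted p = 0.284 with an estimated correlation; median 0.86 under the filter at 5 FPKM), with IGFBP5 at 57 ± 9.09 FPKM and the growth factor IGF2 down to 22.2 ± 1.72 from 83 ± 12.2. BCL2 family genes rose in 9 of 15 cases, fell in 3 and did not pass in 3. The members' median log2 fold change was 0.600 (camera adjusted p = 0.00761, adjusted p = 0.0787 with an estimated correlation), led by BCL2L14 (3.53) and the pro-apoptotic PMAIP1 (3.08). Pseudocounts of 5 and 0.1 gave log2 fold changes of 1.78 and 5.46 for BCL2L14. Epithelial and keratin genes rose in 16 of 29 cases, fell in 5 and did not pass in 8. As a list they had a median log2 fold change of 0.41 (camera adjusted p = 0.0101, adjusted p = 0.447 with an estimated correlation), and the keratin KRT17 stood at 118 ± 17.8 against 4.19 ± 0.476 FPKM. Genes named as persister-cell markers, of which IGF1R itself is a member, rose in 13 of 20 cases, fell in 3 and did not pass in 4. On the log2 scale their median change was 0.64 (camera adjusted p = 0.00681, adjusted p = 0.447 with an estimated correlation). The aldehyde dehydrogenase ALDH1A1 rose by 2.43 (1.27 and 3.23 with pseudocounts of 5 and 0.1) and CD44 fell by 2.53 on the log2 scale. Replication-dependent histone genes rose in 9 of 13 cases, fell in 1 and did not pass in 3. The median over the tested members was 1.38 (camera adjusted p = 0.000921, adjusted p = 0.0593 with an estimated correlation), with H2AC6 at 53 ± 2.01 against 8.14 ± 1.91 FPKM. Under the filter at 5 FPKM the histone median was 2.09.

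Camera did not call the remaining lists in Osi_cIGF1R against DMSO_EV. Members up and down numbered 6 and 3 of 11 for ERBB receptors and ligands (camera adjusted p = 0.241, and 0.0482 without DMSO_EV replicate 3, with a range of 0.0482 to 0.753 over the camera alternatives), where the EGFR ligand BTC reached 10.1 ± 0.148 FPKM from 0.742 ± 0.0618. ATF4 and amino-acid response genes changed in both directions, 8 up and 15 down of 26 (camera adjusted p = 0.241): the stress gene NUPR1 reached 11.4 ± 2.33 FPKM from 0.0845 ± 0.0527 and DDIT4, an inhibitor of mTORC1, 98.3 ± 11.4 from 20.8 ± 3.66, while PHGDH dropped to 14.9 ± 1.14 from 59.6 ± 4.29. Glycolysis and hypoxia genes had 11 members up and 13 down of 30 (camera adjusted p = 0.865), with hexokinase HK2 up by 1.81 (1.19 and 2.07 with pseudocounts of 5 and 0.1). The counts were 11 and 7 of 21 for senescence-associated genes (camera adjusted p = 0.243), 10 and 8 of 25 for p53 target genes (camera adjusted p = 0.632) and 8 and 7 of 21 for mesenchymal genes (camera adjusted p = 0.916), where fibronectin (FN1) stood at 2640.4 ± 666 against 816 ± 221 FPKM. FN1 had a log2 fold change of 1.698, and 2.63 under quantile normalization. YAP and TEAD target genes had 9 up and 7 down of 22 (camera adjusted p = 0.785), with CCN2 down to 2.91 ± 0.30 from 28.8 ± 2.45 FPKM. Among circular RNA biogenesis and m6A factors 6 rose and 13 fell of 28 (camera adjusted p = 0.45): ADAR, an interferon-inducible RNA editing enzyme, reached 133 ± 14.9 FPKM from 21.6 ± 3.36. Of the cell-type lists, 2 alveolar markers rose and 3 fell of 6 (camera adjusted p = 0.865), 3 leukocyte markers and 1 of 6 (camera adjusted p = 0.376), 2 fibroblast markers and 1 of 4, and 0 endothelial markers and 2 of 2, the last 2 lists being too small for camera. In total, camera called 16 of 29 lists, 10 up and 6 down, and 4 of them hold with an estimated correlation: interferon-stimulated, ERK, mitosis and MYC genes. Adjusted over the list alone, the number of called members was the same in 30 of 31 lists and 24 in place of 23 for ATF4. Median, mean and camera direction differed in sign for glycolysis (-0.12, 0.074, up; median 0.029 under quantile normalization), mesenchymal genes (0.032, -0.055, up; median -0.0014 under quantile normalization) and alveolar markers (-0.35, 0.58, down), none of them called. The mesenchymal median ran from -0.0804 to 0.0626 over all alternatives.

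The direct comparison of Osi_cIGF1R with Osi_Lin_EV set the osimertinib groups side by side. They differed both in cIGF1R and in linsitinib, so no difference between them belongs to either alone. Interferon-stimulated genes were higher in Osi_cIGF1R, with OASL at 617 ± 12.8 FPKM in Osi_cIGF1R and 0.702 ± 0.165 in Osi_Lin_EV (SD, n = 3). The immediate early genes FOS and FOSB, which Osi_Lin_EV kept at 215 ± 5.37 and 99.5 ± 6.37 FPKM, stood at 2.13 ± 0.279 and 0.644 ± 0.0432 in Osi_cIGF1R. INSIG1 was 6.77 times as high in Osi_cIGF1R, at 61.2 ± 2.98 against 9.04 ± 0.704 FPKM, and the mitochondrial mRNA COX3 stood at 1586 ± 146 against 9817 ± 1285. Here 3568 genes rose and 4788 fell of 13775 tested (limma, adjusted p under 0.05), and 907 and 603 of these passed an absolute log2 fold change of 1. Median-of-ratios rescaling gave 4050 higher and 4281 lower.

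The 8 largest rises were OASL (log2 fold change 8.51, SE 0.096, limma adjusted p = 1.22e-15), IFIT2 (8.22), IFI27 (7.96), IFIT3 (7.58), OAS2 (7.55), IFIT1 (7.55), IFITM1 (7.12) and the antiviral ubiquitin ligase TRIM22 (6.89). TRIM22 stood at 146 ± 0.636 against 0.241 ± 0.00783 FPKM (SD, n = 3). The 8 largest falls were FOS (log2 fold change -6.11, SE 0.091, limma adjusted p = 8.99e-15), FOSB (-5.93), CCN2, a matricellular growth factor (-3.98), DUSP1, a phosphatase of MAP kinases (-2.77), the mitochondrial transfer RNAs TRNE (-2.72) and TRNH (-2.49), COX3 (-2.63) and MTCO3P12 (-2.49), a nuclear pseudogene that shares sequence with COX3, so that the reads of the pair may not be separable. All 36 interferon-stimulated genes rose. Together they had a median log2 fold change of 5.16 (camera adjusted p = 1.23e-37, adjusted p = 0.000341 with an estimated correlation). The 16 MHC class I antigen presentation genes rose without exception. Over the list the median log2 fold change was 2.96 (camera adjusted p = 1.57e-14, adjusted p = 0.0826 with an estimated correlation), and HLA-B went from 9.73 ± 1.77 to 698 ± 94.9 FPKM. NF-kB and inflammatory cytokine genes rose in 11 of 21 cases, fell in 5 and did not pass in 5. Their median log2 fold change was 0.34 (camera adjusted p = 0.00498, adjusted p = 0.17 with an estimated correlation), and CCL5 went from 0.0602 ± 0.0209 to 71.5 ± 6.5 FPKM. That call ended when Osi_cIGF1R replicate 1, 2 or 3 was left out (camera adjusted p = 0.0967, 0.0645 and 0.0864; medians 0.23, 0.25 and 0.21; median 0.61 under the filter at 5 FPKM), with a range of 0.000889 to 0.17 over the camera alternatives. CD68 was again higher in Osi_cIGF1R, at 428 ± 15.2 against 25 ± 2.39 FPKM, with 2 leukocyte markers up and 2 down of 6 (camera adjusted p = 0.513).

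All 13 mitochondrial DNA-encoded mRNAs fell. The list had a median log2 fold change of -2.13 (camera adjusted p = 3.09e-06, adjusted p = 0.355 with an estimated correlation; median -1.28 under quantile normalization), and COX1 went from 19268 ± 2217 to 4077 ± 388 FPKM and ND5 from 1862 ± 204 to 380.1 ± 69.6 (SD, n = 3). COX1 had a log2 fold change of -2.24, and -0.75 under quantile normalization. Nuclear-encoded oxidative phosphorylation genes fell in 33 of 44 cases, rose in 3 and did not pass in 8. The members' median log2 fold change was -0.51 (camera adjusted p = 0.000204, adjusted p = 0.486 with an estimated correlation). NDUFS8 fell by 1.08 and NDUFA9, both subunits of NADH dehydrogenase, rose by 1.16 on the log2 scale (0.77 and 1.32 with pseudocounts of 5 and 0.1). MYC and ribosome-biogenesis genes fell in 22 of 30 cases, rose in 1 and did not pass in 7. As a list they had a median log2 fold change of -0.55 (camera adjusted p = 1.01e-05, adjusted p = 0.0826 with an estimated correlation), and the nucleolar protein NPM1 went from 462 ± 10.7 to 193 ± 24.7 FPKM. Cholesterol synthesis genes rose in 19 of 24 cases, fell in 2 and did not pass in 3. On the log2 scale their median change was 0.79 (camera adjusted p = 1.92e-07, adjusted p = 0.272 with an estimated correlation), with INSIG1 up by 2.63. Lysosomal genes rose in 18 of 31 cases, fell in 0 and did not pass in 13. The median over the tested members was 0.45 (camera adjusted p = 8.56e-05, adjusted p = 0.418 with an estimated correlation), and the protease CTSL went from 17.9 ± 1.23 to 65.5 ± 12.3 FPKM. Senescence-associated genes rose in 13 of 21 cases, fell in 0 and did not pass in 8. Together they had a median log2 fold change of 0.44 (camera adjusted p = 0.000313, adjusted p = 0.283 with an estimated correlation), among them the cyclin-dependent kinase inhibitor CDKN1A at 74.3 ± 3.28 against 24.2 ± 1.88 FPKM and the plasminogen activator PLAT (2.32). The senescence median was 0.28 without Osi_cIGF1R replicate 3 and 0.25 under the filter at 5 FPKM. FOXO target genes rose in 17 of 21 cases, fell in 3 and did not pass in 1. Over the list the median log2 fold change was 0.51 (camera adjusted p = 0.000624, adjusted p = 0.283 with an estimated correlation), with BTG1 up by 1.06.

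IGF1R was listed at 3.9 ± 0.445 FPKM in Osi_Lin_EV and at 88.2 ± 11 in Osi_cIGF1R (SD, n = 3; log2 fold change 4.18, limma adjusted p = 1.77e-12), and the IGF and insulin receptor signalling genes, of which it is a member, rose in 11 of 17 cases, fell in 1 and did not pass in 5. Their median log2 fold change was 0.57 (camera adjusted p = 0.00146, adjusted p = 0.272 with an estimated correlation). INSR, EGFR and PINK1 did not pass (limma adjusted p = 0.619, 0.519 and 0.932). EGFR passed without Osi_cIGF1R replicate 3 (limma adjusted p = 0.0203; range over the alternatives 0.0203 to 0.94). VDAC1 was lower in Osi_cIGF1R by a log2 fold change of -0.45 (limma adjusted p = 0.0021). ERBB receptors and ligands rose in 6 of 11 cases, fell in 0 and did not pass in 5. The list had a median log2 fold change of 0.35 (camera adjusted p = 0.00391, adjusted p = 0.35 with an estimated correlation), and ERBB3 went from 34.9 ± 2.25 to 67.3 ± 7.87 FPKM. The ERBB median was 0.19 and 0.23 without Osi_cIGF1R replicate 1 and 2 (camera adjusted p = 0.0487 and 0.0334; range over the camera alternatives 0.00337 to 0.35). BCL2 family genes rose in 9 of 15 cases, fell in 4 and did not pass in 2. The members' median log2 fold change was 0.51 (camera adjusted p = 0.0128, adjusted p = 0.17 with an estimated correlation), with the survival factor MCL1 at 102 ± 3.12 against 31.5 ± 0.856 FPKM. Epithelial and keratin genes rose in 15 of 29 cases, fell in 6 and did not pass in 8. As a list they had a median log2 fold change of 0.27 (camera adjusted p = 0.0117, adjusted p = 0.4 with an estimated correlation), with KRT17 up by 4.11 on the log2 scale. Under quantile normalization the epithelial median was 0.61 and the glycolysis median 0.34. Glycolysis and hypoxia genes rose in 14 of 30 cases, fell in 5 and did not pass in 11. On the log2 scale their median change was 0.18 (camera adjusted p = 0.0175, adjusted p = 0.424 with an estimated correlation), with HK2 at 13.7 ± 1.55 against 1.55 ± 0.144 FPKM. Mitosis and G2/M genes, low in both groups, rose in 16 of 30 cases, fell in 3 and did not pass in 11. The median over the tested members was 0.29 (camera adjusted p = 0.0274, adjusted p = 0.428 with an estimated correlation), and AURKB went from 1.77 ± 0.422 to 4.91 ± 0.566 FPKM.

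A further 3 lists lost the call both with an estimated correlation and under the filter at 5 FPKM. ATF4 and amino-acid response genes rose in 14 of 26 cases and fell in 6. Together they had a median log2 fold change of 0.39 (camera adjusted p = 0.0275, adjusted p = 0.4 with an estimated correlation), with STC2 at 16.1 ± 0.486 against 3.15 ± 0.182 FPKM. The list passed neither without Osi_cIGF1R replicate 2 (median 0.203, camera adjusted p = 0.0561) nor without replicate 3 (0.22, 0.129), nor under the filter (0.0064, 0.248), and without replicate 1 the median was 0.25 (0.0487; range over the camera alternatives 0.02 to 0.4). Replication-dependent histone genes rose in 6 of 13 cases and fell in 1. Over the list the median log2 fold change was 0.51 (camera adjusted p = 0.0399, adjusted p = 0.272 with an estimated correlation). Without Osi_cIGF1R replicate 3 or Osi_Lin_EV replicate 1 the camera adjusted p was 0.0506 and 0.0507, under median-of-ratios rescaling 0.0543, and under the filter 0.416 with a median of 0.34 (range over the camera alternatives 0.0246 to 0.416). Genes named as persister-cell markers, IGF1R included, rose in 10 of 20 cases and fell in 4. Their median log2 fold change was 0.25 (camera adjusted p = 0.0274, adjusted p = 0.483 with an estimated correlation), and under the filter the camera adjusted p was 0.248 (range over the camera alternatives 0.00678 to 0.483). The mitosis call ended under the filter (camera adjusted p = 0.0611) and without Osi_Lin_EV replicate 1 (0.0507), with a range of 0.0127 to 0.428 over the camera alternatives. Lists not called had 11 members up and 7 down of 26 for ERK outputs (camera adjusted p = 0.175), 4 and 6 of 30 for DNA replication (camera adjusted p = 0.713), 11 and 7 of 28 for mitophagy (camera adjusted p = 0.12) and 9 and 7 of 28 for autophagy (camera adjusted p = 0.405). Over the scalings 4 to 7 ERK outputs, 4 to 8 autophagy genes and 0 to 2 lysosomal genes fell. The numbers were 10 and 5 of 21 for mesenchymal genes (camera adjusted p = 0.13), 11 and 5 of 25 for p53 targets (camera adjusted p = 0.109), 10 and 4 of 22 for YAP and TEAD targets (camera adjusted p = 0.219) and 8 and 11 of 28 for circular RNA factors (camera adjusted p = 0.769). Alveolar markers had 1 up, LAMP3, and 5 down of 6 (camera adjusted p = 0.219), fibroblast markers 2 and 1 of 4, and endothelial markers 1 and 0 of 2. Camera called 19 of 29 lists, 16 up and 3 down, and 1 of them, the interferon-stimulated genes, holds with an estimated correlation. Adjusted over the list alone, the number of called members was the same in 26 of 31 lists. It was 19 in place of 18 for ERK outputs, 8 in place of 10 for DNA replication, 20 in place of 19 for mitosis, 14 in place of 16 for autophagy and 17 in place of 16 for NF-kB genes. Median, mean and camera direction differed in sign for ERK outputs (0.22, -0.19, up), circular RNA factors (-0.00089, 0.057, up; the median ran from -0.042 to 0.062 under other scalings) and alveolar markers (-0.61, 0.41, down), none of them called. The ERK median ran from 0.106 to 0.25 over all alternatives.

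**Figure D2:**
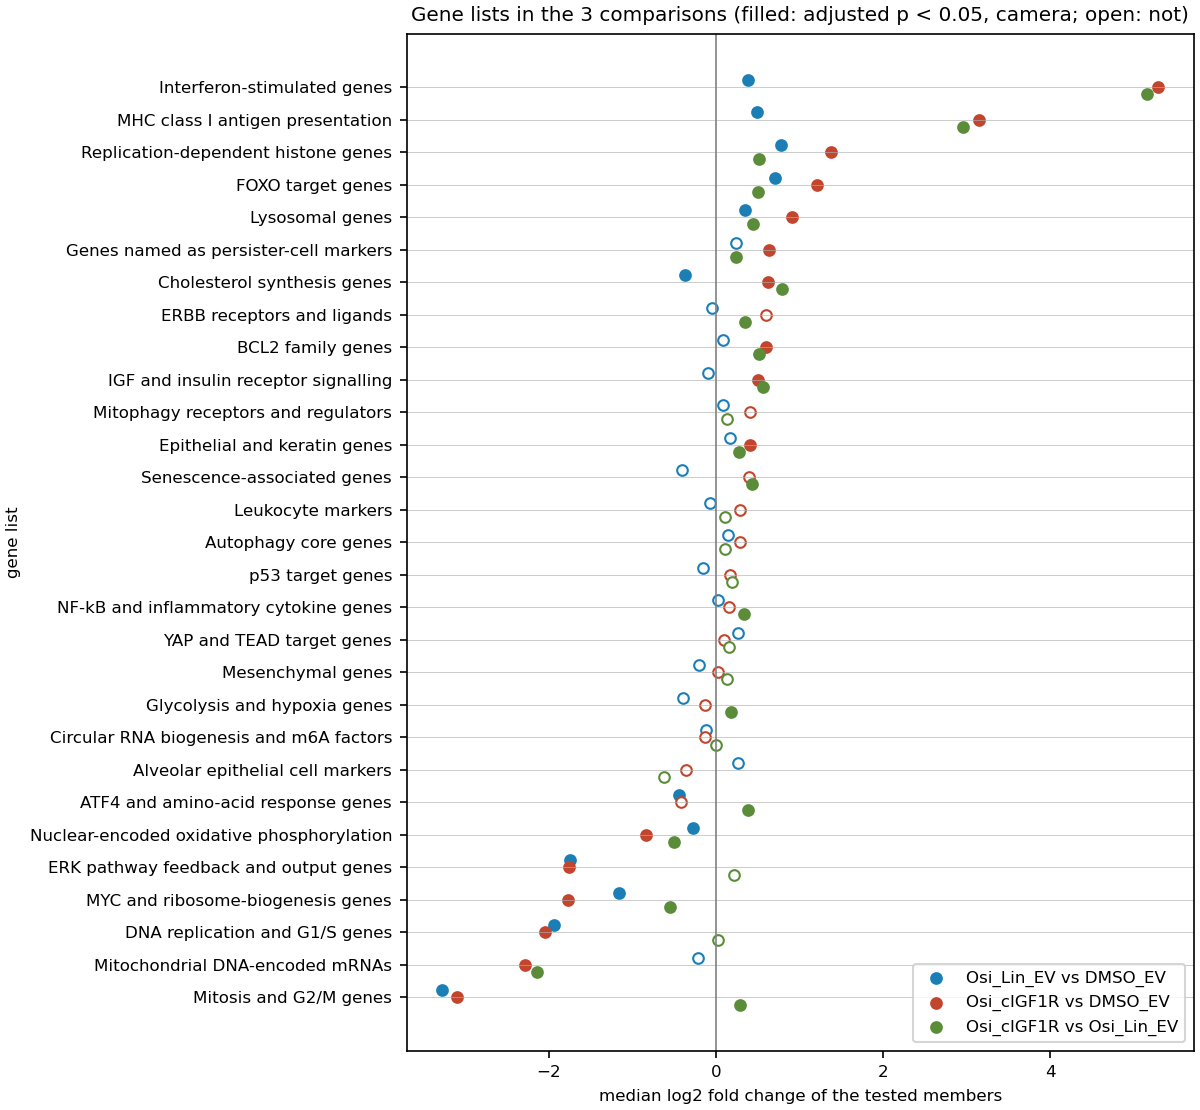
Median log2 fold change of the tested members of 29 gene lists (horizontal axis, log2 scale) in the 3 comparisons; filled points have a camera adjusted p under 0.05 and open points do not. The interferon-stimulated genes lie at 5.29 and 5.16 in the comparisons with Osi_cIGF1R and at 0.39 in Osi_Lin_EV against DMSO_EV, and the mitochondrial DNA-encoded mRNAs at -2.28, -2.13 and -0.21.

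Set against the shared DMSO_EV libraries, the cell-cycle genes fell in both treated groups: the 30 mitosis and the 30 DNA replication genes were lower in each, as were the 30 MYC and ribosome-biogenesis genes, and 23 of 26 ERK outputs were called in the same direction. With an estimated correlation the camera call of the DNA replication list held in Osi_Lin_EV (adjusted p = 0.0304) and not in Osi_cIGF1R (adjusted p = 0.0649), and those of the mitosis, MYC and ERK lists held in both. Cholesterol synthesis genes split, with 9 of 24 called in opposite directions and 4 in the same. Over all genes, 5021 were called in the same direction in both comparisons, 2519 up and 2502 down, where independent lists of these sizes would share 1325 and 1162. A further 616 were called in opposite directions, against 2507 for independent lists. Each of these 616 was also called in the direct comparison. That follows from the fit, since the direct difference of such a gene is larger than either of its changes against DMSO_EV. At an absolute log2 fold change of 1 in both, 880 genes changed in the same direction and 7 in opposite ones. Across genes, which are not independent replicates, the log2 fold changes had a Pearson's r of 0.63, where 20 simulations of unchanged groups against the same controls gave a mean of 0.496 and a maximum of 0.538. The covariance was 0.417 against a simulated 0.0101, a difference of 0.407, and the signs matched for 71.9% of genes against a simulated 66.7%. The simulated r and share of matching signs follow from sharing controls where nothing else changes. They are therefore no baseline for groups that did change. The simulated covariance, which does not have this limit, was small beside the observed one. The simulations, which held no change in any group, gave 0 shared calls. They therefore do not measure how far the shared controls raise the count of shared calls. The 3 control libraries cannot be split so that each part keeps 2, so part of the excess of shared calls over independent lists may come from the shared controls.

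**Figure D3:**
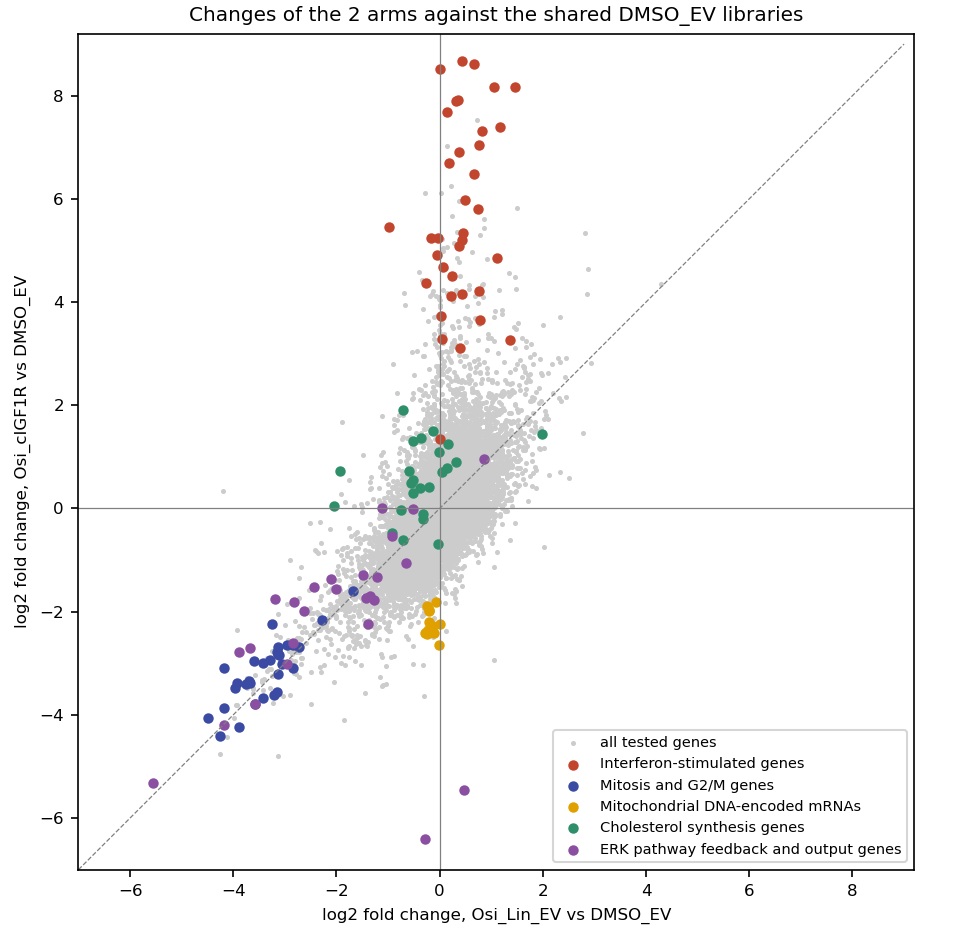
Log2 fold change against DMSO_EV of each of the 13775 tested genes in Osi_Lin_EV (horizontal axis) and Osi_cIGF1R (vertical axis), with 5 gene lists in colour and the line of equal change dashed. Mitosis genes lie near that line, interferon-stimulated genes rise along the vertical axis up to 8.66, mitochondrial DNA-encoded mRNAs lie below it near -2.28, and FOS and FOSB lie at -6.40 and -5.45 there and at -0.29 and 0.48 in Osi_Lin_EV.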

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

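The comparisons and camera tests in this part were chosen before the data were examined. The rescaling without mitochondrial genes and quantile normalization of the lists were chosen only after the results were seen. The cholesterol synthesis genes differed between the treated groups: the list was called lower than DMSO_EV in Osi_Lin_EV (median log2 fold change -0.37, camera adjusted p = 0.00235) and higher in Osi_cIGF1R (median 0.62, camera adjusted p = 0.00395). The direct test of that difference gave a median of 0.79 (camera adjusted p = 1.92e-07), with 21 of 24 members called. Lists were flagged only where the calls against DMSO_EV were opposite and the direct test was called too. That test is therefore no separate support. In all, 9 members were called in opposite directions against DMSO_EV and 4 in the same. With an estimated correlation none of these camera calls held (adjusted p = 0.703, 0.447 and 0.272), and over the camera alternatives the adjusted p ran from 0.000318 to 0.703, from 0.00153 to 0.447 and from 1.1e-08 to 0.272. Under 3 other scalings these camera calls held, with medians of -0.43 to -0.34, 0.58 to 0.66 and 0.76 to 0.85.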

How the results depend on the processing

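The rescaling without mitochondrial genes, quantile normalization of the lists and the splits of the libraries were tests chosen only after the results were seen. The other alternatives were planned. DESeq2, voom and edgeR alternatives for counts were not run because the values are not counts. With an absolute log2 fold change of 1, the counts were 1266, 3004 and 1510 genes in Osi_Lin_EV with DMSO_EV, Osi_cIGF1R with DMSO_EV and Osi_cIGF1R with Osi_Lin_EV, and 880 in the overlap. Here the smaller count follows from the added condition. With an estimated correlation 5, 4 and 1 lists were called in place of 12, 16 and 19, and with fry 26, 26 and 25. Fry does not compare a list with other genes, and the cause was not tested further. The 4 results that reversed were fry tests of lists that camera did not call: IGF and insulin receptor signalling in Osi_Lin_EV against DMSO_EV (median -0.088, fry adjusted p = 0.0468, range over the camera alternatives 0.636 to 0.984), alveolar markers in Osi_cIGF1R against DMSO_EV (-0.35, 3.14e-06, 0.709 to 0.957), ERK outputs (0.22, 0.000173, 0.115 to 0.682) and alveolar markers (-0.61, 0.000308, 0.198 to 0.4) in Osi_cIGF1R against Osi_Lin_EV. Fry's direction was up for IGF signalling and for the alveolar markers in each comparison, and down for ERK outputs, against the sign of these medians. It had the sign of the list means, 0.15, 0.58, -0.19 and 0.41 in the order given. Why the set tests differ was not tested. Leaving out each replicate gave 6137 to 7775, 8516 to 9325 and 7130 to 8513 genes, 11 to 15, 16 to 18 and 16 to 19 lists, and 4227 to 5300 shared genes. Over 5501 alternative values of 297 results for named genes, 5493 kept direction and side of the threshold, 0 were weaker and 8 passed where the reported value did not. These 8 belong to EGFR. Over 1386 values of 87 results for lists, 1290 kept both, 52 lost the call, 40 gained it and 4 reversed. The replicate numbers gave no sign of pairing the libraries: 9 correlations of deviations between libraries with the same number lay between -0.315 and 0.0358, 0 of them over 0.1, and 1 of 18 correlated best with its own number. Whether libraries with the same number were prepared together is not said by the labels and cannot be decided from these correlations. With the replicate block 6838, 9204 and 7963 genes, 12, 16 and 19 lists and 4726 shared genes were called. Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. As many genes were called in 1, 1 and 1 of them, with real counts of 7241, 9499 and 8356 and highest others of 0, 1 and 1. As many lists were called in 2, 4 and 1, with real counts of 12, 16 and 19 and highest others of 14, 16 and 14. Every other split mixes the compared groups unevenly and so keeps part of their difference, while it widens the spread within each side. The counts from other splits are therefore no reference for groups without a difference. Pseudocounts of 0.1 and 5 moved 31 and 104 of 291 called log2 fold changes of named genes by over 1.5 times. Read depth is unknown, so what it limits for low genes could not be stated.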

Other observations

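All lists, genes and tests in this part were chosen only after the results were seen, except the medians of the lists fixed in advance. Interferon genes were listed in Osi_cIGF1R: IFNL1, a type III interferon, stood at 17.9 ± 1.46 FPKM (SD, n = 3) and at 0 in each DMSO_EV library, and IFNB1, a type I interferon, at 2.06 ± 0.357 and at 0 in the 6 other libraries. IFNL2 and IFNL3, near-identical copies whose reads cannot be assigned to either with certainty, stood at 9.26 ± 1.59 and 9.8 ± 1.87. Of 5 interferon genes tested against DMSO_EV 4 rose in limma and 0 did in Osi_Lin_EV, under each of 3 other scalings too. These 4 passed the filter only through the Osi_cIGF1R libraries, so that count was largely set by the filter. IFNE, also tested, was lower in Osi_cIGF1R than in Osi_Lin_EV (-0.55, limma adjusted p = 0.00559). IFNA1, not tested, was listed at 0.121 ± 0.0358 FPKM in Osi_cIGF1R and 0.406 ± 0.125 in DMSO_EV. Of 12 nucleic acid sensors and their effectors 11 rose in Osi_cIGF1R against DMSO_EV (median 2.66) and 8 in Osi_Lin_EV (6 to 8 over the scalings), where 2 fell (1 to 2), CGAS (-0.999, limma adjusted p = 1.53e-05) and STING1 (-0.23, 0.0384). DDX58, which encodes the RNA sensor RIG-I, stood at 121 ± 3.15 FPKM in Osi_cIGF1R, 3.47 ± 0.48 in Osi_Lin_EV and 2.31 ± 0.192 in DMSO_EV, IFIH1, the sensor MDA5, at 70.8 ± 1.03, 1.41 ± 0.224 and 0.771 ± 0.163, and OAS1 at 329 ± 2.09, 4.83 ± 0.643 and 2.69 ± 0.358 in the same order. MAVS, the adaptor of RIG-I and MDA5, did not pass in Osi_cIGF1R against DMSO_EV (limma adjusted p = 0.666) and rose in Osi_Lin_EV (0.32, 0.0266). All 13 complement genes tested rose in Osi_cIGF1R and 10 in Osi_Lin_EV (8 to 10 over the scalings), with the protease C1S at 411 ± 26.6 FPKM in Osi_cIGF1R, 49.4 ± 3.44 in Osi_Lin_EV and 17.4 ± 2.19 in DMSO_EV. C4A and C4B are near-identical copies. The median of the complement genes in Osi_cIGF1R lay between 3.72 and 3.85 over the scalings.

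Of 40 cytosolic ribosomal protein genes 38 fell in Osi_cIGF1R against DMSO_EV (37 to 38 over the scalings; median -0.98) and 1 in Osi_Lin_EV (1 to 8), and 0 rose in either (0 to 2 and 0 to 4 over the scalings). RPL5 stood at 107 ± 16.1 FPKM in Osi_cIGF1R, 470.2 ± 14.5 in Osi_Lin_EV and 558 ± 17.3 in DMSO_EV, and RPS9 and RPS27 did not pass (limma adjusted p = 0.975 and 0.858). Among 23 immediate early genes 10 rose and 9 fell in Osi_Lin_EV, and 3 and 16 in Osi_cIGF1R. ATF3 stood at 8.53 ± 0.29 FPKM in Osi_cIGF1R, 36.6 ± 2.01 in Osi_Lin_EV and 13.6 ± 2.07 in DMSO_EV, while IER3 was low in both treated groups at 14.1 ± 2.98 and 14.5 ± 0.40 against 120.4 ± 6.22. Of 5 structural noncoding RNAs tested, 1, RMRP, fell in Osi_cIGF1R (limma adjusted p = 0.0225) and 0 in Osi_Lin_EV. RMRP stood at 162 FPKM in DMSO_EV replicate 2 and at 11.4 and 6.87 in replicates 1 and 3. In Osi_cIGF1R it stood at 2.18 FPKM in replicate 1 and at 0 in replicates 2 and 3.

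Interferon-stimulated genes were higher in Osi_cIGF1R than in DMSO_EV by a median of 5.29 on the log2 scale. The authors' scaling was argued against as the whole cause, since the smallest median under 3 other scalings was 5.30. RNA from leukocytes was argued against too: their markers had a median of 0.173 FPKM and an upper quartile of 1.32, against a median of 161 for the interferon-stimulated genes, although CD68, the most abundant marker, stood at 428 ± 15.2. Among what stays open is how far osimertinib without cIGF1R would raise the list. The median was 0.39 in Osi_Lin_EV, which also had linsitinib, so the drug and the circular RNA cannot be told apart here. The other groups had EV in place of the cIGF1R construct. The circular RNA and the construct that delivered it therefore cannot be told apart either.

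Mitochondrial DNA-encoded mRNAs were lower in Osi_cIGF1R than in DMSO_EV, with a median log2 fold change of -2.28 (camera adjusted p = 8.54e-06, but adjusted p = 0.447 with an estimated correlation). Scaling was argued against as the whole cause, since the median nearest to 0 under 3 other scalings was -1.40. A change in mitochondrial content stays open: nuclear-encoded oxidative phosphorylation genes had a median of -0.84, and neither mitochondrial DNA nor mass was measured.

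IGF1R was higher in Osi_cIGF1R by 4.11 on the log2 scale. A change in copy number or transcription across the region was argued against, since TTC23 had the largest change among 4 tested neighbours, 1.004 (SE 0.11), against an SE of 0.11 for IGF1R. Of the 4, 2 rose and 1 fell. These neighbours cannot speak to a change limited to IGF1R itself, which was not tested. Reads from the cIGF1R construct counted at IGF1R are a candidate explanation that stays open, as the table holds a value per gene and none per exon or junction.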
